A study of Pinus radiata with 12 samples.

How the data were processed

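Gene expression was measured in stem tissues of Pinus radiata on 12 oligonucleotide arrays with 2 dyes. Per the labels' protocols, clonal saplings of a single genotype carried a lanolin paste around the stem base that held 1 mg ethephon, a compound that releases ethylene in plant tissue, or no ethephon. Bark, developing xylem (the scraped cambial region) and xylem (the wood left after scraping) were taken 1 or 8 weeks after treatment. Each of the 6 groups, a tissue at a week, had 2 arrays. On each array RNA of 1 treated biological replicate was hybridised against a pool of control RNA of the same tissue and week, and both arrays of a group used the same control pool. The ratios therefore leave out the spread between control plants. The labels give more than one account of how many saplings make up a replicate. Groups were taken from the labels before the data were examined, as were the tests, the rule for named probes and most alternatives.

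Ethephon RNA carried Cy3 in all week 1 groups and in xylem at week 8, and Cy5 in bark and developing xylem at week 8, per the labels. No group held both dye orientations, so a dye bias of a probe stays in the ratio of its group. It cancels in the difference between weeks in xylem, between tissues at week 1, and between bark and developing xylem at week 8, and it is doubled in the difference between weeks in bark and in developing xylem. Bark lay on slide 2 and xylem on slide 3. Developing xylem lay on slide 1 with its week 8 arrays and replicate 1 of week 1, and on slide 4 with replicate 2 of week 1. Slides 1 and 2 were scanned in 1 session and slides 3 and 4 in another.

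The deposited scanner files hold linear intensity values per spot, per the file headers made with Agilent Feature Extraction 10.7.3.1. The files give median rather than mean foreground signals, so medians were used where means had been planned. The authors' deposited tables of comparisons hold a log2 fold change and a raw and adjusted p-value for each of 180873 spots, control spots included. Per the submitters' processing notes limma was used for them, and its version, design and background correction are not given in the sources used here. Each table was matched to its group, and its direction set, by its correlation with the ratios computed here. The authors' deposited unlogged channel tables equal the scanner medians spot by spot and were not used separately.

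Signals were background-corrected with normexp (offset 50) and normalised by loess within each array, with control spots and non-uniform spots at weight 0. Non-uniform spots were left out, and 6987 probe values were missing as a result. Ratios were turned to ethephon over control by the dyes in the labels, and spots of a probe were averaged. Of 175613 probes, 105327 were well above background in at least 1 channel on at least 2 of the 12 arrays and were tested. The 6 group means were fitted to all 12 arrays with limma 3.58.1 (R 4.3.3), with 6 residual and 4.68 prior degrees of freedom. Each mean was tested against 0, weeks were compared within tissues, and tissues were compared by a moderated F-test within weeks. Tests were two-sided with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. Levels between tissues at week 1 were compared on the Cy3 signals of 6 arrays after loess and quantile normalisation of average intensities between arrays (Aquantile). P-values and SEs rest on 1 spread per probe, pooled within all 6 groups and moderated by limma. They do not measure the spread between the 2 arrays of a single group, and the number of arrays limits precision.

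The files pair the probes with no gene names, and no annotation was used here. The 23 gene lists fixed beforehand were therefore not analysed here. Probes whose identifiers differ only in a final a, b or c were taken as probes of 1 assembly. The rule for named probes was the largest changes past the threshold with the same sign on both arrays, with 1 probe per assembly and at most 2 per direction in a comparison, and the smallest p for differences between weeks and tissues. A probe not well above background in a channel on either array is given by its fitted fold, without an exact size. The dim channel after loess and Aquantile was floored at the lowest signal among probes well above background. This floor changed none of the folds, so they are not lower bounds. Such folds are open to dye bias. Values of the other probes of an assembly, and differences between weeks or tissues, are fitted values and give no exact size where a channel was not well above background.

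The tests were run on simulated data with 105327 probes and the spread of the real fit. In the simulation of bark at week 1, 65 of 66 probes changed by 2 on the log2 scale were recovered, 35 of 67 changed by 1 and 0 of 67 changed by 0.5, with 7 false calls among 107. The noise was independent, with the same spread of a probe in every group, and without dye bias or a shared control pool. These numbers thus do not reflect the agreement of the real replicates of a group, such as r = 0.09 in bark at week 1. Groups of 2 arrays allow no count of other splits of the samples and no outlier test. Alternatives covered background correction, normalisation within and between arrays, filters, blocks for replicate number, plant code, slide and scan session, the arrays fitted, an additive model, raw median signals, array weights, each array left out in turn and a threshold on the log2 ratio. The additive model had terms for tissue, week and dye in place of the group means. It holds no response confined to a tissue at a week, so calls lost or gained there cannot be put down to dye. The block for scan session, centring on spike-in controls and leaving out arrays without spike-in signal were chosen after seeing the data. That centring also left out the 3 arrays without such signal, 1 of them in developing xylem at week 1.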

Results

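The data comprised 12 arrays with 2 dyes, 2 for each of 6 groups (bark, developing xylem and xylem of Pinus radiata, 1 and 8 weeks after treatment). Every array set RNA of stems treated with 1 mg ethephon, which releases ethylene in plant tissue, against a control pool of the same tissue and week. The main comparison was ethephon against control within each tissue and week, followed by comparisons between tissues and between weeks. Between 25.1% and 44.0% of probes were well above background in Cy3 and between 28.5% and 51.8% in Cy5. Median probe signals ran from 48.5 to 116 in Cy3, over a background of 29 to 36, and from 50 to 100 in Cy5, over a background of 39 to 43. Values below are mean log2 ratios of ethephon over control with the SE of the limma fit, and adjusted p-values are those of limma. This SE rests on the spread pooled over all groups and does not measure the agreement of the 2 arrays of a group. Probes are given by the identifiers of the array, since the files do not pair them with gene names.

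**Figure D1:**
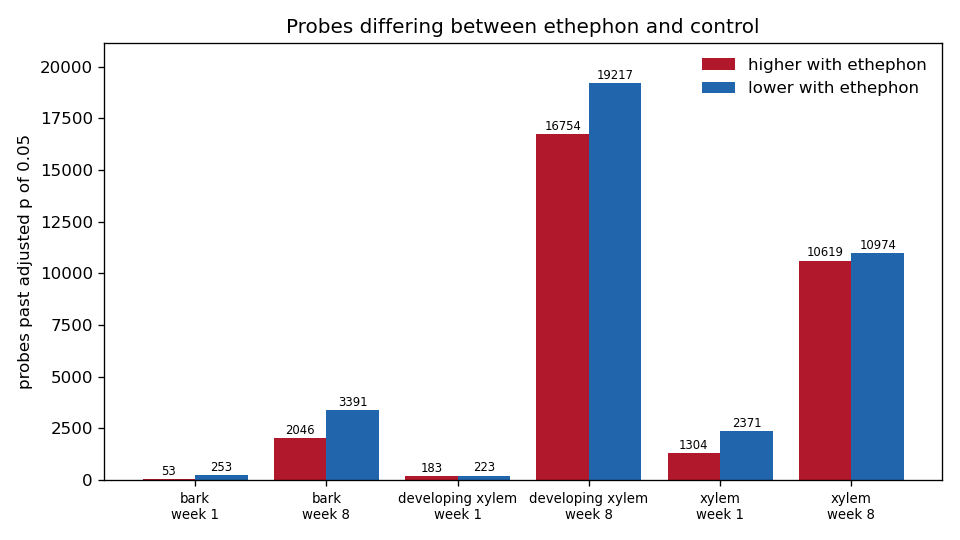
Number of probes past an adjusted p of 0.05 (vertical axis) that were higher (red) or lower (blue) with ethephon in each tissue and week, from 2 arrays per group. Developing xylem at week 8 had 16754 higher and 19217 lower probes, and bark at week 1 had 53 and 253.

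In bark at week 1, 306 of 105316 probes differed between ethephon and control, 53 higher and 253 lower. CO199585a rose by 3.43 ± 0.31 (SE, n = 2; adjusted p = 0.00303) and Contig6530a by 3.28 ± 0.49 (adjusted p = 0.0239). Both other probes of Contig6530 also rose, by 3.17 and 3.23, whereas CO199585b stood at -0.08 beside 3.26 for CO199585c. TC117508c had a log2 ratio of -3.01 ± 0.50 (adjusted p = 0.0420) and Contig848a of -2.99 ± 0.25 (adjusted p = 0.00177). The other probes of TC117508 did not pass (-1.03 and -1.36), and Contig848b passed at -2.15. None of the 4 named probes passed with Agilent's processed signals or with these arrays fitted alone, and CO199585a, Contig6530a and TC117508c did not pass in the additive model. TC117508c did not pass with array weights, and neither it nor Contig6530a without the 3 arrays that lacked spike-in signal. Contig6530a lost the threshold when any 1 week 1 array of bark or developing xylem was left out, and TC117508c without any 1 of the 12 arrays other than those of bark at week 8. At least 2 probes passed in the same direction in 71 assemblies, 12 higher and 59 lower. Fitting these arrays alone, or keeping only probes well above background in both channels of all arrays, left 0 calls by limma (6250 and 1399 probes at an unadjusted p under 0.05), and 88 were left without replicate 2 and 157 without either week 1 array of developing xylem. If no probe changed, a share of 0.05 of the 105316 and 27355 probes tested in these 2 settings would reach such an unadjusted p. The 6250 and 1399 are therefore not by themselves evidence of change. The split was 28 higher and 2493 lower with median centring, 1153 and 985 with raw median signals, 9 and 73 with Agilent's processed signals, and 404 and 729 in the additive model.

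In bark at week 8, 2046 probes rose and 3391 fell. TC142108b rose by 4.49 ± 0.37 (SE, n = 2; adjusted p = 0.000259), with TC142108c at 4.31 and TC142108a, which did not pass, at 0.50. Contig32903c rose by 4.17 ± 0.20 (adjusted p = 9.05e-06), and Contig32903a by 1.17. Contig10727a had a log2 ratio of -4.31 ± 0.27 (adjusted p = 4.45e-05), and its other probes stood at -3.59 and -4.09, both past the threshold. Contig10727a did not pass in the additive model, which holds no response confined to bark at week 8. TC136608c stood at -3.43 ± 0.64 (adjusted p = 0.0130), and its other probes did not pass (-0.68 and -2.87). It lost the threshold with processed signals and without either array of the group. At least 2 probes passed in the same direction in 1364 assemblies, and 4 assemblies held probes of both directions. Without replicate 1 the count was 1720, and without replicate 2 it was 859, with 555 higher and 304 lower. The split was 1322 higher and 985 lower with median centring, 1235 higher and 21504 lower with raw median signals, and 434 higher and 97553 lower with centring on spike-in controls. It was 927 and 1459 with Agilent's processed signals, 569 and 1134 among probes well above background throughout, 1225 and 1493 in the additive model, and 893 and 1671 with a log2 ratio of at least 1.

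In developing xylem at week 1, 183 probes rose and 223 fell. Contig38929a rose by 1.97 ± 0.32 (SE, n = 2; adjusted p = 0.0395) and Contig38929b by 1.51. Single arrays of Contig38929a stood at 2.62 and 1.32. Contig6530c rose by 1.88 ± 0.30 (adjusted p = 0.0376), and its other probes did not pass (1.45 and 1.01). Contig6530c lost the threshold with Agilent's processed signals, median centring, raw median signals and the additive model, and Contig38929a with raw median signals. Both lost it without the 3 arrays that lacked spike-in signal, and TC150876b did not pass in the additive model. Leaving out 1 array ended the call of Contig38929a for 7 of the 12 arrays (both of bark at week 1, replicate 1 of developing xylem at week 1 and all 4 of xylem) and that of Contig6530c for the 6 of week 1. TC121605b was lower with ethephon by a fitted 23.8-fold (adjusted p = 1.27e-05), with single arrays at -5.07 and -4.07 on the log2 scale. It was not well above background in the ethephon channel, so this fold gives no exact size, while TC121605c stood at 0.01. TC150876b had a log2 ratio of -4.39 ± 0.13 (adjusted p = 2.77e-07), whereas the other probes of this assembly stood on the opposite side of 0, at 1.14 and, past the threshold, 1.27. Spike-in controls gave signal on replicate 2 and not on replicate 1. Without replicate 1 the count was 45, with 36 higher and 9 lower, and without replicate 2 it was 158, with 26 higher and 132 lower. It was between 201 and 223 without any 1 array of bark or week 1 array of xylem, and leaving out all 3 arrays without spike-in signal left 39 (30 higher, 9 lower). The split was 381 higher and 320 lower with Agilent's processed signals, 29 and 1385 with median centring, 10 and 980 with raw median signals, and 383 and 102 among probes well above background throughout. With centring on spike-in controls, which rested on replicate 2 alone, it was 53 and 68170. The count rose to 4894 (2057 higher, 2837 lower) with these arrays fitted alone, 3397 (1653 and 1744) in the additive model and 768 (364 and 404) with array weights, and it was 226 (74 and 152) with a log2 ratio of at least 1.

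In developing xylem at week 8, 16754 probes rose and 19217 fell, which was 34.2% of those tested. The median change was 1.67-fold among higher and 2.10-fold among lower probes. Contig28887b rose by 5.50 ± 0.34 (SE, n = 2; adjusted p = 1.49e-06), with its other probes at 4.55 and 3.60. Contig14397c rose by 5.07 ± 0.71 (adjusted p = 0.000282), with Contig14397b at 4.06 and Contig14397a, which did not pass, at 0.42. Contig14397c did not pass in the additive model. Pta16504a stood at -6.46 ± 0.73 (adjusted p = 6.40e-05), and Pta16504b at -3.97. Pta95082555c stood at -6.39 ± 0.84 (adjusted p = 0.000178), and its other probes at -4.09 and -5.95. At least 2 probes passed in the same direction in 10190 assemblies, and 248 assemblies held probes of both directions. Neither array held spike-in signal, and without replicate 1 the count was 22181, with 8187 higher and 13994 lower. The split was 24251 higher and 16977 lower with Agilent's processed signals, 45690 and 6208 with median centring, and 35451 and 14280 with raw median signals. More probes were lower than higher with these arrays fitted alone (8857 higher, 13054 lower), in the additive model (9785 and 10850), among probes well above background throughout (7356 and 8346) and with a log2 ratio of at least 1 (4759 and 10360).

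In xylem at week 1, 1304 probes rose and 2371 fell. Contig39420b rose by 2.96 ± 0.27 (SE, n = 2; adjusted p = 0.000359) and Contig39420a by 2.25. Contig6104c rose by 2.70 ± 0.56 (adjusted p = 0.0284), with its other probes at 2.62 and 1.92. It lost the threshold with processed signals, in the additive model and without either array of the group. TC121605b stood at -6.67 ± 0.20 (adjusted p = 2.40e-07), while TC121605c passed at -0.73. Contig39374c stood at -5.81 ± 0.22 (adjusted p = 1.27e-06), and its other probes at -4.12 and -4.72. At least 2 probes passed in the same direction in 838 assemblies, and 3 assemblies held probes of both directions. Without replicate 1 the count was 585 and without replicate 2 it was 821. The split was 168 higher and 3018 lower with median centring, 81 and 2928 with raw median signals, and 366 and 4677 with centring on spike-in controls. Among probes well above background throughout it was 1334 and 1605. The count was 856 (261 higher, 595 lower) with Agilent's processed signals, 631 (153 and 478) in the additive model, 7530 (3020 and 4510) with array weights and 1520 (307 and 1213) with a log2 ratio of at least 1.

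In xylem at week 8, 10619 probes rose and 10974 fell, which was 20.5% of those tested. TC141059a was higher with ethephon by a fitted 70.2-fold (adjusted p = 0.000338) and TC137342a by a fitted 49.1-fold (adjusted p = 0.000448). Neither was well above background in the control channel of either array, so these folds give no exact size. Single arrays stood at 5.46 and 6.80 for TC141059a, and at 5.29 and 5.94 for TC137342a, on the log2 scale. The other probes of TC141059 stood at 4.74 and 2.54, and those of TC137342 at 5.57 and, not past the threshold, 1.28. TC140772b stood at -8.48 ± 0.37 (SE, n = 2; adjusted p = 7.33e-07), with its other probes at -7.72 and -8.13. Contig8864a stood at -8.15 ± 0.63 (adjusted p = 2.51e-05), with single arrays at -7.11 and -9.19, and Contig8864c at -7.33. At least 2 probes passed in the same direction in 5451 assemblies. Spike-in controls were 12.6-fold and 10.9-fold brighter in the control than in the ethephon channel of the 2 arrays, and without replicate 1 or replicate 2 the count was 10662 (4042 higher, 6620 lower) or 10867 (5135 and 5732). The split was 13106 higher and 11659 lower without background correction, 14801 and 13881 with slide as a block, 13569 and 9166 with Agilent's processed signals, 27761 and 5605 with median centring, 27912 and 3583 with raw median signals, and 104946 and 82 with centring on spike-in controls. More probes were lower than higher with these arrays fitted alone (4462 higher, 6811 lower), in the additive model (5098 and 6227), among probes well above background throughout (3991 and 5366) and with a log2 ratio of at least 1 (2710 and 5161).

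**Figure D2:**
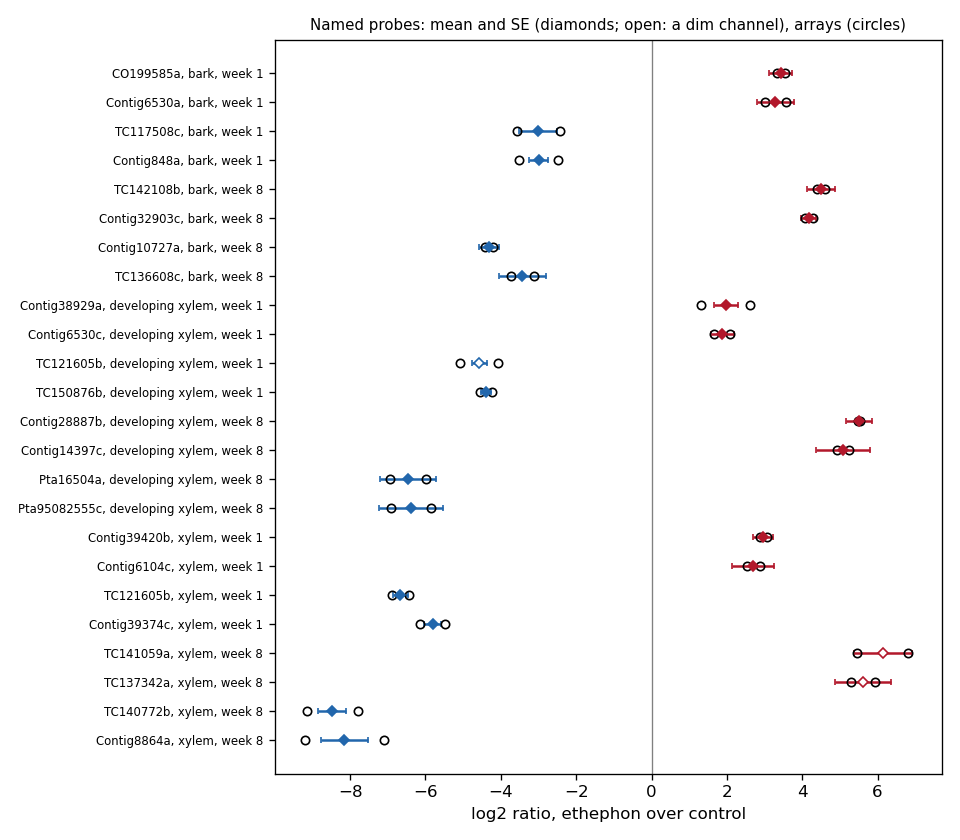
Log2 ratio of ethephon over control (horizontal axis) of the named probes in their comparison, as the group mean with its SE (diamonds and bars; red higher, blue lower) and the single arrays (circles, n = 2). Both arrays lay on the same side of 0 for each probe by the rule for naming them, and the SE rests on the spread pooled over all groups. Open diamonds mark fitted values of probes with a channel not well above background on either array, which give no exact size.

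Calls overlapped between tissues at week 8. In developing xylem and xylem, which had opposite dye orientations, 9937 probes were called in the same direction, against 3691 for independent lists, and 1455 in opposite directions. Bark and xylem shared 1716 calls in the same direction (560 for independent lists) and 266 in opposite directions (555). Bark and developing xylem shared 1730 in the same direction (944) and 1148 in opposite directions (913), so both exceeded the number for independent lists. All 3 tissues shared 569 higher probes (32.8 for independent lists) and 397 lower probes (64.5). Contig32903c and Contig28887b were among the probes that rose in each tissue at week 8. At week 1 developing xylem and xylem shared 122 calls in the same direction (7.29 for independent lists), and 2 probes rose and 0 fell in all 3 tissues. Ethephon RNA carried the same dye in all week 1 groups, and in bark and developing xylem at week 8. A dye bias of a probe would also give shared calls in the same direction there. The calls of all groups also rest on 1 spread per probe, so the lists are not independent. Probes are not independent of each other, and codes in the labels recur between groups, for treated and control RNA alike in bark and xylem at week 8. The labels do not say whether the same plants gave both tissues, so shared calls are not shown to come from separate plants.

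Responses differed between weeks. In xylem, where dye bias cancels, 10205 probes differed, 4818 with a higher and 5387 with a lower ratio at week 8, and 81.0% of them had the larger change at week 8. The split was 5847 higher and 4621 lower with Agilent's processed signals, 24641 and 2398 with median centring, 27070 and 1396 with raw median signals, and 3447 and 3438 without replicate 2 of week 8. TC140772a went from -1.07 at week 1 to -7.72 at week 8 (adjusted p = 2.36e-06), and Contig3772c from -1.90 to 3.46 (adjusted p = 7.39e-07). Contig39374a had fitted ratios of -4.72 and -0.03 (adjusted p = 1.85e-06), but was not well above background in the ethephon channel at week 1 or in either channel at week 8. In developing xylem 18093 probes differed, 93.8% of them with the larger change at week 8, and in bark 1047 differed. ScionT37T4311030b went from -0.37 to -4.59 in developing xylem (adjusted p = 1.26e-05) and Contig14400b from -0.14 to 2.68 in bark (adjusted p = 0.000545). In bark and developing xylem the dye of the ethephon RNA changed between weeks. In bark 5 probes differed when its 4 arrays were fitted alone, and without replicate 2 of week 1, the 1 array of developing xylem outside slide 1, 9103 differed in developing xylem, with week 1 resting on 1 array that lacked spike-in signal and the spread taken from all groups. Without replicate 1 of week 1, 4307 differed in xylem and 11512 in developing xylem, and in xylem 5930 differed without replicate 2 of week 1 and 6342 without replicate 1 of week 8. The count in bark was 448 without replicate 2 of week 1, 514 and 522 without replicate 1 and 2 of week 8, and 487 without either week 1 array of developing xylem.

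Responses also differed between tissues. At week 1, where dye bias cancels, 381 probes differed among the tissues. Contig39374a stood at -4.72 in xylem, -0.66 in bark and -0.37 in developing xylem (adjusted p = 1.11e-05), and TC150876b at -4.39 in developing xylem, -1.72 in xylem and 0.29 in bark (adjusted p = 1.11e-05). The ethephon channel of Contig39374a in all 3 tissues, and of TC150876b in xylem, was not well above background on either array, so these are fitted values. Between pairs of tissues at week 1, 19 probes differed between bark and developing xylem, 348 between bark and xylem and 421 between developing xylem and xylem. At week 8, 31756 probes differed among the tissues, and 27586 between bark and developing xylem, which had the same dye orientation. The week 8 arrays of each tissue lay on a slide of their own, and each tissue had its own control pool. Slide and control pool thus cannot be told apart from tissue there. Developing xylem lay on slide 1, whose arrays lacked spike-in signal. Contig14614a stood at -6.30 in xylem, -0.08 in bark and -0.11 in developing xylem (adjusted p = 2.48e-07), where neither channel was well above background in bark or developing xylem. At week 1 the count was 574 without replicate 1 of bark and 219 without its replicate 2, 163 and 205 without replicate 1 and 2 of developing xylem, and 192 and 170 without those of xylem. Without replicate 2 of bark the count at week 8 was 20903. A model with additive terms for tissue, week and dye gave 248 probes for either week, since it holds 1 tissue difference for both.

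Levels in ethephon-treated tissue were compared at week 1, and 23662 probes (22.5%) differed in Cy3 signal among the tissues. Between developing xylem and xylem 22438 differed, against 11640 between bark and xylem and 9779 between bark and developing xylem. ScionGCgreg1a was higher in bark than in xylem, by 8.44 ± 0.37 on the log2 scale (SE, n = 2; adjusted p = 0.000813). Pta106882551b had a bark minus xylem difference of -10.24 ± 0.68 (adjusted p = 0.00138). The sign of the difference was the same in the control pools, in Cy5, for 99.8% of the probes called between bark and xylem. Tissue and slide largely coincide, and RNA extraction differed by tissue, so these cannot be told apart from tissue. The control pools lay on the same arrays, so the shared sign does not separate them. The count was 11315 without replicate 1 of bark, 10731 without its replicate 2 and 14955 without replicate 2 of developing xylem.

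Replicate arrays correlated, across probes, with r = 0.09 in bark at week 1, 0.56 in bark at week 8, 0.52 in developing xylem at week 1, 0.82 in developing xylem at week 8, 0.52 in xylem at week 1 and 0.76 in xylem at week 8. Group means of the same dye orientation correlated with r between 0.06 and 0.31 over 7 pairs, and those of opposite orientation between -0.03 and 0.44 over 8 pairs. With slide as a random block, whose estimated correlation was -0.13, the counts were 772 in bark at week 1, 9268 in bark at week 8, 921 in developing xylem at week 1, 43253 in developing xylem at week 8, 7079 in xylem at week 1 and 28682 in xylem at week 8. With scan session as a random block they were, in the same order, 340, 5775, 434, 36596, 3943 and 22254. The negative correlation with slide narrows the SE where both arrays of a group share a slide. The higher counts with slide are therefore to be read with care. In the authors' deposited tables, 314 probe spots passed an adjusted p of 0.05 in bark at week 1, 4682 in bark at week 8, 679 in developing xylem at week 1, 35020 in developing xylem at week 8, 4199 in xylem at week 1 and 24539 in xylem at week 8. The log2 fold changes in the authors' deposited table correlated with the ratios computed here with r between 0.985 and 0.996 across probes. Of the 306 calls in bark at week 1, 283 passed in the same direction in the authors' deposited table, as did 33239 of the 35971 in developing xylem at week 8. The share was lowest in bark at week 8, with 4548 of 5437 (83.6%). The direction of each table was set by these same ratios, so the shared direction is no check on orientation. In xylem at week 8 the authors' deposited table held 12905 higher and 11634 lower probe spots, against 10619 and 10974 probes here.

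**Figure D3:**
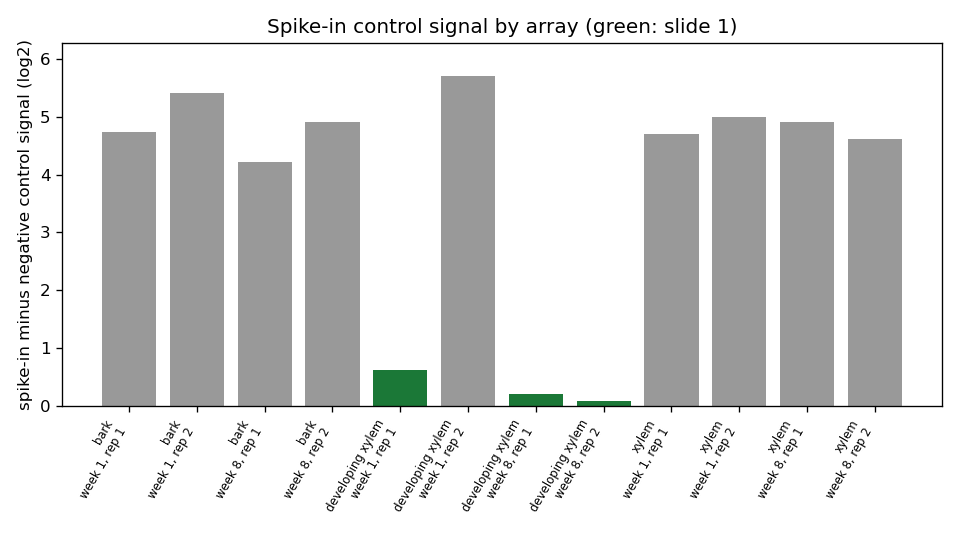
Signal of the 10 spike-in controls minus that of the negative controls (vertical axis, log2) on each of the 12 arrays, with the arrays of slide 1 in green. The 3 arrays of slide 1 lay between 0.08 and 0.62 and the other 9 between 4.22 and 5.70.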

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

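The tests of shared direction at week 8, replicate spread, control pools and scaling were chosen after their results were seen, and the tests of dye bias at week 1 and of the dim control channel before. Responses differed between weeks, by the contrast of week 8 and week 1, for 1047 probes in bark, 18093 in developing xylem and 10205 in xylem. They differed between tissues, by a moderated F-test, for 381 probes at week 1 and 31756 at week 8. Slide and control pool went with tissue at week 8 and cannot be told apart from it.

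Named probes whose log2 ratio differed between weeks are given as week 8 minus week 1. In bark the difference was -2.52 for CO199585a, 3.95 for TC117508c, 3.86 for Contig32903c and -3.21 for Contig10727a. In developing xylem it was 4.67 for TC121605b, 4.52 for TC150876b, 4.12 for Contig28887b, 6.64 for Contig14397c, -6.41 for Pta16504a and -6.45 for Pta95082555c. In xylem it was -1.54 for Contig39420b, 6.35 for TC121605b, 5.50 for Contig39374c, 5.80 for TC141059a, 5.50 for TC137342a, -7.88 for TC140772b and -7.90 for Contig8864a. The differences of CO199585a, TC121605b, TC150876b, Contig39420b, TC141059a and TC137342a are fitted values without an exact size, since in a group compared a channel was not well above background on either array. For TC121605b this held for both channels at week 8 in both tissues, so its ratios there are not measured changes.

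Named probes whose log2 ratio differed between tissues are given by the largest difference between any pair of tissues. At week 1 it was 2.86 for Contig848a, 6.67 for TC121605b, 4.67 for TC150876b, 2.94 for Contig39420b and 5.48 for Contig39374c. At week 8 it was 1.48 for Contig32903c, 4.49 for Contig10727a, 3.05 for TC136608c, 2.18 for Contig28887b, 7.27 for Contig14397c, 4.52 for Pta16504a, 5.02 for Pta95082555c, 5.68 for TC141059a, 5.45 for TC137342a, 8.17 for TC140772b and 6.57 for Contig8864a. In at least 1 tissue a channel was not well above background on either array for all 5 of these probes at week 1, and at week 8 for Contig10727a, Contig28887b, TC141059a, TC137342a, TC140772b and Contig8864a, so their differences are fitted values without an exact size.

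Spike-in controls, which entered the alternatives with centring but not the counts reported first, showed signals that differed between arrays. On 3 arrays, all of slide 1, they lay within 1 log2 unit of the negative controls. In xylem at week 8 they were 12.6-fold and 10.9-fold brighter in the control than in the ethephon channel.

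More probes were lower than higher with ethephon at week 1 in bark and in xylem. A dye bias would turn such probes higher where ethephon RNA carried Cy5, but in bark and developing xylem at week 8 their median log2 ratio was -0.08 (-0.0766) for those of bark and -0.08 (-0.0845) for those of xylem. The scaling within arrays remains a candidate explanation in bark, where the share of higher probes reached 53.9% with raw median signals. In xylem that share was at most 37.7% over the 5 scalings, which argues against scaling as the whole cause there. With a filter for probes well above background throughout, which is not a scaling, the share in xylem was 45.4%. An effect of ethephon remains open and was not tested apart from these.

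Many probes were called at week 8 in developing xylem and in xylem. A dye bias would move probes called in both groups in opposite directions, and 87.2% of them moved in the same direction. Calls that came only from a dim control channel in xylem would not become more frequent among bright probes, those well above background in both channels. The called share of bright probes was 30.4% at week 8 and 6.03% at week 1, a ratio of 5.05. Over all probes tested it was 20.5% and 3.49%, and the count was 5.88 times that at week 1. The increase was thus present, though no larger, among bright probes, which argues against a dim control channel as the whole cause. These values do not bear on the quality or amount of RNA in the control pool, which was not tested and may contribute beside an effect of ethephon.

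More probes were called at week 8 than at week 1 in each tissue. The median absolute difference between the 2 arrays of a group was on average 0.899 times as large at week 1 as at week 8. The fit shared 1 spread per probe among all groups, so a group with a larger spread of its own could gain calls. With the arrays of each group fitted alone, limma called 0 and 5088 probes in bark at weeks 1 and 8. These counts were 4894 and 21911 in developing xylem, and 2706 and 11273 in xylem. Week 8 thus still held more calls, though fewer than in the main fit. With array weights xylem had 7530 and 18358. With median centring the order was turned in bark, with 2521 calls at week 1 and 2307 at week 8. Each group had 1 control pool, so a pool that stood apart from other control plants and an effect of ethephon cannot be told apart.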

How the results depend on the processing

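Blocking by scan session, centring on spike-in controls and leaving out arrays without spike-in signal were chosen after seeing the data. Where a value moved, the cause was not tested unless the alternative itself gives it. No background correction, no filter, Aquantile (which leaves ratios as they were), plant code, scan session and the replicate block kept each count they were run for within 1.5 times. No normalisation between arrays, run for tissue levels, gave 38126 probes. Same-numbered arrays showed no clear shared deviation (r between -0.22 and 0.12 over 15 pairs of groups). Arrays sharing a plant code character within a week gave r between -0.22 and 0.20 over 7 pairs. Such values cannot exclude a pairing of samples. With the replicate block 266 probes were called in bark at week 1, 5053 in bark at week 8, 280 and 35277 in developing xylem, 3488 and 20513 in xylem, 944, 17184 and 9527 between weeks in bark, developing xylem and xylem, 331 and 30436 between tissues, and 18691 for levels.

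With a log2 ratio of at least 1 also required, 2564 probes were left in bark at week 8, 226 and 15119 in developing xylem, and 1520 and 7871 in xylem. Agilent's processed signals gave 82 and 2386 in bark, 701 in developing xylem at week 1, 856 in xylem at week 1, 317 between weeks in bark and 132 between tissues at week 1. Median centring gave 2521 and 2307 in bark, 1414 in developing xylem at week 1, 33366 in xylem at week 8, and 6668, 40768 and 27039 between weeks in bark, developing xylem and xylem. Raw median signals gave 2138 and 22739 in bark, 990 in developing xylem at week 1, 32703, 33024 and 28466 between weeks, and 815 between tissues at week 1. The median log2 ratio of all probes shifted by 0.19 in developing xylem at week 8 with processed signals, and with median centring by -0.24 in bark at week 1, 0.36 in developing xylem at week 8 and 0.12 in xylem at week 8. With raw signals it shifted by -0.44 in bark at week 8, -0.17 and 0.12 in developing xylem, and -0.16 and 0.24 in xylem. With centring on spike-in controls, which also left out the 3 arrays without such signal and so rested on 1 array in developing xylem at week 1, it shifted by -0.94 in bark at week 8, -0.81 in developing xylem at week 1, and -0.20 and 3.69 in xylem. That centring gave 97987 in bark at week 8, 68223 in developing xylem at week 1 (against 39 without these arrays and uncentred) and 105028 in xylem at week 8, and could not be run in developing xylem at week 8.

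Requiring signal well above background in both channels of all arrays, which left fewer probes, gave by limma 0 (1399 at an unadjusted p under 0.05) and 1703 in bark, 15702 in developing xylem at week 8, 9357 in xylem at week 8, 80, 9059 and 4990 between weeks, 43 and 13750 between tissues, and 10158 for levels. Slide as a random block gave 772 and 9268 in bark, 921 in developing xylem at week 1, 7079 in xylem at week 1, 1143 between tissues at week 1, and 62545 for levels, where its estimated correlation was -0.71. For levels both arrays of bark, and both of xylem, shared a slide. A negative correlation narrows the SE of such means, so the higher counts are to be read with care. Fitting only the arrays compared, with fewer degrees of freedom, gave by limma 0 in bark at week 1 (6250 at an unadjusted p under 0.05), 4894 and 21911 in developing xylem, 11273 in xylem at week 8, 5 between weeks in bark and 218 between tissues at week 1. With no change, a share of 0.05 of the probes tested in bark at week 1 would reach such an unadjusted p. These were 105316 with only the arrays compared and 27355 under the strict filter. Additive terms for tissue, week and dye gave 1133 and 2718 in bark, 3397 and 20635 in developing xylem, 631 and 11325 in xylem, 5078 between weeks and 248 between tissues. Array weights gave 768 in developing xylem at week 1, 7530 in xylem at week 1 and 763 between tissues at week 1. Leaving out the 3 arrays without spike-in signal gave 142 in bark at week 1, 39 in developing xylem at week 1 and 109 between tissues at week 1.

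Leaving out each array in turn, with a lone array taken to vary like the other groups, gave 88 to 458 and 859 to 6169 in bark, 45 to 538 and 22181 to 35795 in developing xylem, and 585 to 4099 and 10662 to 22992 in xylem. Between weeks it gave 448 to 1217 in bark, 9103 to 17936 in developing xylem and 4307 to 11560 in xylem, between tissues 163 to 574 and 20903 to 30963, and for levels 10731 to 23677. Of the 24 values of named probes, each kept its direction wherever an alternative gave a value, which was for 4 under the strict filter, 20 with centring on spike-in controls and 8 without the 3 arrays. The threshold was lost by 8 in the additive model of tissue, week and dye, 7 with processed signals, 4 when only the arrays compared were fitted, 2 with raw median signals, 1 each with median centring, array weights and centring on spike-in controls, and 4 of the 8 without the 3 arrays, and of 288 values with 1 array left out by 31. The named probes were chosen in these data for large ratios with the same sign on both arrays. Leaving out 1 array could therefore not reverse a direction, so the kept directions there are no test. Leaving out an array of another group leaves the ratio as it was and alters only the spread, and the 288 values include these cases. Gene list tests, counts of annotated genes, and for levels the dye, plant and shared-spread alternatives were not run, the last since levels already used 6 arrays alone. Signal over background limited which probes entered: 27356 were well above background in both channels of all arrays.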

Other observations

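One probe, TC118453a, passed the threshold in all 6 groups and was chosen after its values were seen. It was higher with ethephon each time, by 1.37 in bark at week 1 and 3.14 at week 8, 1.83 and 1.88 in developing xylem, and 1.76 and 3.09 in xylem on the log2 scale. In all, 49371 probes passed in at least 1 group, 33938 of them in 1 group alone.

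TC141059a and TC137342a, which were higher with ethephon in xylem at week 8, stood at 0.46 and 0.17 in developing xylem at week 8 without passing the threshold. In bark at week 8 TC141059a passed at 3.55 and TC137342a, at 2.46, did not. At week 1 they stood at -2.44 and -2.70 in bark and at -3.15 and -3.71 in developing xylem, also without passing, and with the ethephon channel of developing xylem not well above background on either array. TC121605b, which was lower in developing xylem and xylem at week 1, was not well above background in either channel in the other groups.

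The arrays differed in spike-in signal. The log2 ratio of Cy5 over Cy3 for these controls was 0.81 and 0.78 in bark at week 8, against -0.14 and -0.33 in bark at week 1 and 3.66 and 3.44 in xylem at week 8. In bark at week 1 the control pool, hybridised to both arrays, differed between them by a median of 0.09 on the log2 scale, and the treated samples by 0.19. In xylem at week 1 these values were 0.36 and 0.37.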
